A study of Homo sapiens with 3 samples.

How the data were processed

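Total RNA from 3 cultures of LvM3b, a human colon adenocarcinoma line, was measured on Illumina bead arrays, 1 array per group: control cells, cells overexpressing miR-483-5p and cells overexpressing miR-551a. The sample label names the first microRNA as miR-483 and the series text as miR-483-5p. Cells were grown in DMEM with serum, RNA was isolated with the Ambion miRVANA kit and biotinylated cRNA was made with the Ambion MessageAmp kit, per the labels' protocols. How the overexpression was made, the scanner software and its settings are not given in the sources used here.

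The authors deposited a table of non-normalized intensity values for 48803 probes in each array, with a detection score, a fraction between 0 and 1, beside each intensity per the file headers. In the values this fraction lies near 1 for bright probes, so a score above 0.99 was read as a detection p below 0.01. The authors also deposited a normalized intensity table, and the series matrix holds identical values. In that table the control column equals the non-normalized one, and the miR-551a column is its non-normalized column multiplied by 0.968, the control median over its own. The column named for miR-483 is a constant multiple, 0.934, of the non-normalized miR-551a column over all 48803 probes, while its ratio to the non-normalized miR-483 column ran from 0.519 to 2.49. It therefore carried no values of the miR-483-5p array and was not used for it; all miR-483-5p results rest on the non-normalized table.

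The main values were computed here from the non-normalized intensities of the 3 arrays together with neqc of limma 3.58.1 in R 4.3.3, which corrects the background from the detection scores, adds an offset of 16 and quantile-normalizes on the log2 scale. The inferred background had a mean of 76.2 (SD 9.10 across background probes) in the control array, 80.6 (10.3) in the miR-483-5p array and 79.0 (9.46) in the miR-551a array. A probe entered a comparison if it carried a gene symbol and was detected in at least 1 of the arrays compared; results for both overexpressing arrays used probes detected in at least 1 of the 3 arrays. Targets given only as UniGene clusters, 12646 of 37846, were treated as having no symbol. Of the 25200 symbols, 15712 matched a current symbol in the RefSeq gene table, 3021 matched 1 gene by an older symbol and 6467 were kept as listed.

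With 1 array per group there is no test between groups, and no p-value, SE or SD across arrays was computed. Differences of log2 intensity were described at a threshold of 2-fold. Where 1 array did not detect a probe, its dim value was replaced by the lowest detected level of that array where that was higher, and the ratio is given as "at least", a bound that holds for background-corrected values only; no ratio is given where neither detected it. Named genes followed a rule fixed before the data were examined: the 12 largest differences each way per overexpressing array and for both together, and 6 each way between the 2 overexpressing arrays, among probes brighter than the median of detected probes, 1 probe per gene, without provisional symbols; every member of a fixed list with a 2-fold difference; up to 4 leading members of lists that stood apart; and all members of the creatine and reported target lists. The values of 1 gene that this rule names are not reported here. The 31 gene lists were also fixed then. A list with at least 5 measured genes, each taken as the mean of its detected probes, was described by the percentile of its median among 10000 random lists of equal size matched on mean expression in 20 bins, and was said to stand apart below the 0.5 or above the 99.5 percentile.

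Both differences from control contain the same control array. Its contribution, for a control array with the same noise as the others, was estimated from 1000 simulated sets of 3 unchanged arrays. The noise was taken by intensity from the difference between the 2 overexpressing arrays. The planned analysis of genes with microRNA seed sites was not run, because no 3′ UTR sequence was used here.

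The pipeline was tested on simulated data for miR-483-5p against control. A first simulation, with a noise SD of 0.17 set by hand and detection from a normal curve, was followed by a second with noise (SD 0.140, from the difference between the overexpressing arrays) and detection taken from the arrays; the second was added after the first one's rate of calls among unchanged probes had been seen. In the first and second, 100% and 100% of 50 probes made 4-fold higher passed 2-fold, as did 96.0% and 96.0% of 50 made 4-fold lower; of 50 probes each made 2-fold higher or lower, 38.0% and 38.0% passed in the first and 44.0% and 46.0% in the second. A list of 20 genes lowered by 0.4 fell below every random list in both, and 1 and 5 of 200 unchanged lists stood apart. The rates among unchanged probes are given beside the measured counts.

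Alternatives were no background correction, normexp with offset 50, median centring, cyclic loess, stricter and looser detection filters, probes brighter than the median, a 1.5-fold threshold, gene means, the brightest probe per gene, and, for miR-551a, the deposited normalized table. Median scaling of all 3 non-normalized columns was added after the data were seen. Figures and lists were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.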

Results

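Expression profiles were obtained from LvM3b colon cancer cells as controls, with overexpression of miR-483-5p and with overexpression of miR-551a, to find genes that the microRNAs suppress. Each group had 1 array and there were no replicates, so every difference below is between single cultures and carries no error. The median intensity over 48803 probes was 84.9 in the control, 88.0 in the miR-483-5p and 87.7 in the miR-551a array, and 13814, 13291 and 13925 probes were detected. No probe carried the symbol MIR483 or MIR551A, so the arrays gave no measure of the microRNAs themselves; IGF2, the host gene of miR-483, was not detected in any array, and no probe carried the symbol MEGF6.

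In the miR-483-5p array, genes of amino acid synthesis and stress signalling were among the most reduced relative to control. DDIT4, an inhibitor of mTORC1, was 3.02-fold lower and the cytokine IL33 3.10-fold lower. Asparagine synthetase ASNS was 2.61-fold lower, the mitochondrial PEP carboxykinase PCK2 2.59-fold and the serine synthesis enzyme PSAT1 2.33-fold. Basal keratin KRT17 was 12.5-fold higher and the actin-binding protein TAGLN 9.60-fold higher, and the mucin MUC5AC 3.05-fold higher; without background correction KRT17 was 7.20-fold and TAGLN 4.82-fold higher. ATP2C2 (2.46-fold), PAPSS2 (2.46-fold), the ERK phosphatase DUSP6 (2.42-fold), ACOX2 (2.31-fold), the intestinal antigen GPA33 (2.29-fold), the receptor KIT (2.26-fold) and EPB41L4A-AS1 (listed as TIGA1, 2.20-fold) were also lower. Among the higher genes were the aldo-keto reductases AKR1C2 (2.59-fold), AKR1B10 (2.53-fold) and AKR1C4 (2.01-fold), S100A10 (2.55-fold), ALDH1A1 (2.46-fold), FABP5 (2.21-fold) and PLA2G2A (2.16-fold). KIFC1 was 2.12-fold, ANLN 2.09-fold and KPNA2 just above 2-fold higher. Probes of 1 gene did not always match: a further AKR1C2 probe differed by -0.07 on the log2 scale, a further PCK2 probe by -0.19, and a further TAGLN probe was detected in neither array.

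Of 13759 probes compared, 79 were at least 2-fold higher and 95 at least 2-fold lower in the miR-483-5p array, together 1.26%. Unchanged simulated probes passed the same threshold in 0.919% of 14152 cases with noise taken from the arrays. With the noise first set by hand 1.24% of 17713 cases passed, so the total is close to what the simulations gave. Both rates lay above the 0.487% measured between the overexpressing arrays, so they do not decide how much of the total is noise. The simulated calls were dim probes: of 7045 unchanged probes brighter than the median, 0 passed, against 18 higher and 21 lower among 6879 such measured probes. The simulated noise was normal with an SD of 0.140, which leaves almost no room for a 2-fold call among brighter probes. Between the overexpressing arrays, which supplied that SD, 0 were higher and 7 lower of 6874 brighter probes. The genes above came from the brighter probes of the comparison of miR-483-5p with control, except TAGLN, which was dim in control and is named for its difference in both arrays. Without background correction the counts were 15 higher and 19 lower.

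Fixed gene lists showed coordinated differences in the miR-483-5p array: 8 of 26 measured lists stood apart, 3 high and 5 low. The nominal rate gives 0.26, and in the simulation with noise from the arrays 2.5% of unchanged lists stood apart. Random lists hold genes drawn singly, and the simulated noise was independent for each probe. Neither rate therefore allows for genes of 1 list that vary together between cultures. Cell cycle genes were higher in 22 of 23 cases (median 0.44, percentile 100), including BIRC5 (0.80), CCNA2 (0.77) and TYMS (0.66); MKI67, not detected in control, was at least 1.59-fold higher. All 11 heat shock genes, a list fixed as a sign of sample handling, were higher (median 0.40, percentile 100), led by HSPA1B (0.66), DNAJB1 (0.50) and BAG3 (0.48). MYC targets of ribosome and polyamine synthesis had a median of 0.23 (percentile 99.93), with SRM at 0.73 and NOP56 (listed as NOL5A) at 0.49; this call ended among brighter probes (percentile 99.36) and under median scaling (99.40). The integrated stress and unfolded protein list was low (median -0.35, percentile 0; -0.22 for genes detected in both arrays), with ASNS at -1.28, PSAT1 at -1.22, ATF3 at -0.95 and TRIB3 at -0.94. TGF-beta targets (median -0.46, percentile 0) were led by ID3 (-0.86), ID1 (-0.62, the mean of probes at -1.05 and -0.18), BAMBI (-0.60) and CCN2 (listed as CTGF, -0.59). Immediate early genes, which respond within minutes to growth factors and handling, had a median of -0.28 (percentile 0.02), with EGR1 at -1.05, ATF3 at -0.95 and FOS at -0.63. Histone genes (median -0.49, percentile 0) included H2BC21 (-0.67), and all 8 metallothioneins were lower (median -0.35, percentile 0.01), led by MT1F (-0.61). Outside these lists, the interferon-induced ISG15 was 2.71-fold lower, the hypoxia gene HILPDA (listed as HIG2) at least 1.99-fold higher and the WNT inhibitor NOTUM at least 2.35-fold higher.

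**Figure D1:**
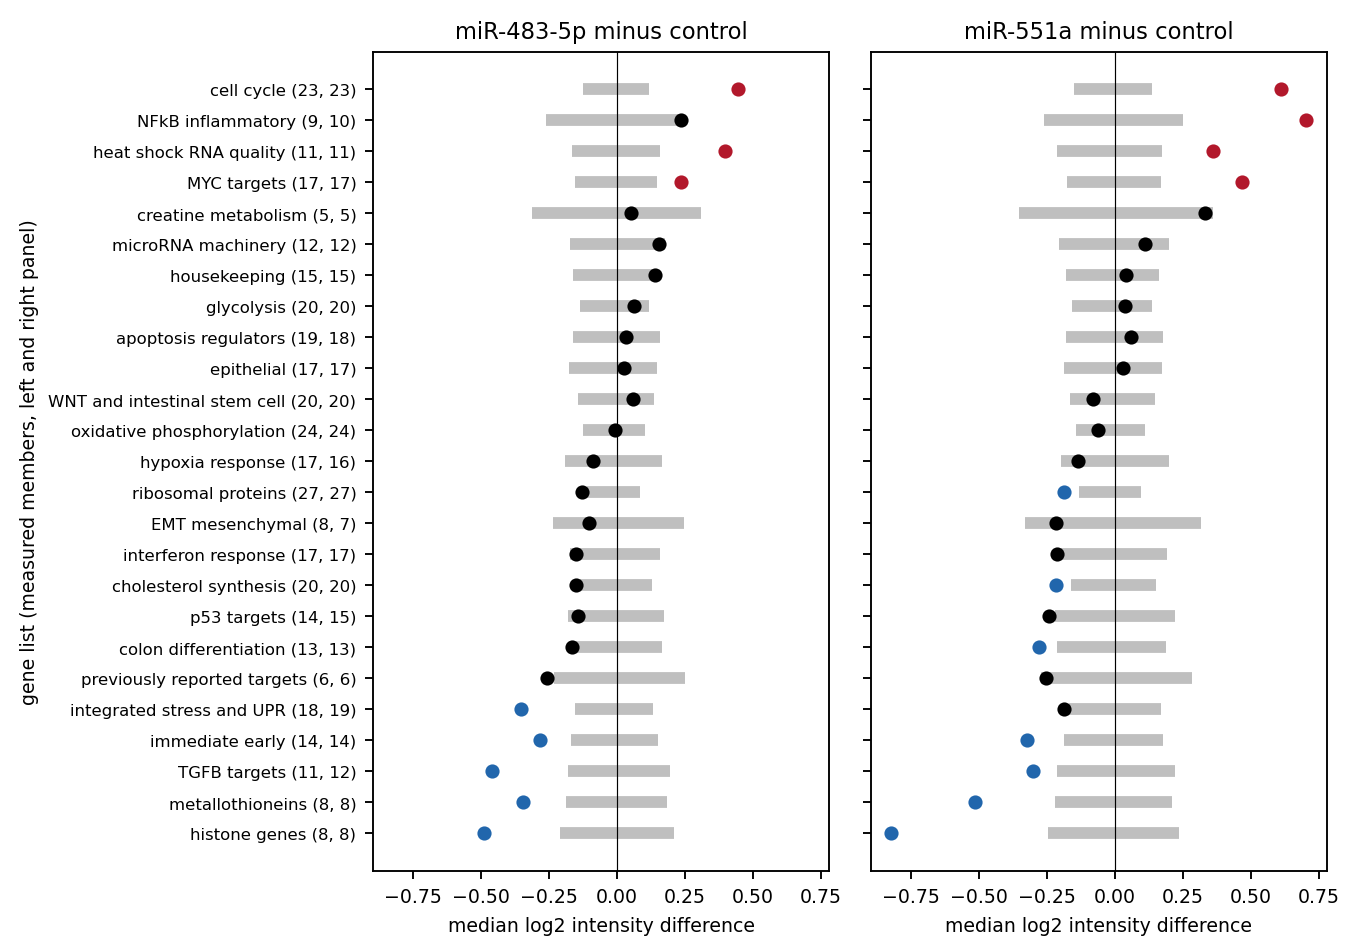
Median log2 intensity difference from control (x axis) of each fixed gene list (y axis, with its measured genes in the left and right panel) for the miR-483-5p array on the left and the miR-551a array on the right. Points are list medians, red where the list stood apart high and blue where low, grey bars leave out the lowest and highest 2.5% of 10000 matched random lists, and the cell cycle point lies at 0.44 on the left and 0.61 on the right.

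In the miR-551a array, KRT17 was 32.8-fold, TAGLN 21.7-fold and KRT6B 7.76-fold higher than in control, and without background correction 18.1-fold, 10.2-fold and 4.82-fold. Epithelial membrane protein EMP1 was 3.81-fold higher, S100A10 3.55-fold, the annexin ANXA1 2.94-fold, keratin KRT8 2.81-fold and the chemokine CXCL8 (listed as IL8) 2.70-fold at 1 probe and 2.49-fold at the other. Among probes brighter than the median, DDIT4 was 4.14-fold lower, ACOX2 2.72-fold, the immediate early factor EGR1 2.70-fold and IL33 2.65-fold. KIT (2.59-fold), ASNS (2.58-fold), ID3 (2.57-fold), GPA33 (2.57-fold), ID1 (2.55-fold), TXNIP (2.44-fold) and PAQR8 (2.42-fold) were lower too. PLA2G2A (2.98-fold), MUC5AC (2.97-fold), FABP5 (2.95-fold) and ALDH1A1 (2.72-fold) were higher. The KIT and ALDH1A1 probes here are not those named for miR-483-5p. At these probes KIT was 3.02-fold lower and ALDH1A1 2.19-fold higher in the miR-483-5p array. RPS29 was 2.55-fold lower at 1 probe, but its other probes differed by 0.01, -0.03 and -0.09 on the log2 scale; a further TAGLN probe, not detected in control, was at least 1.58-fold higher.

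Of 14039 probes, 138 were at least 2-fold higher and 134 lower in the miR-551a array, together 1.94%. The simulations, made for miR-483-5p against control, passed 0.919% and 1.24% of unchanged probes, so part of this total may be noise. Among the 7019 probes brighter than the median, 47 were higher and 35 lower. The balance moved with the settings: the deposited normalized table, which is median scaling without background correction, gave 57 higher and 28 lower, 67.1% higher in place of 50.7%. Leaving out the background correction alone gave 58.8% and median centring alone 59.0%.

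Of 25 measured lists, 4 stood apart high and 7 low in the miR-551a array, against 0.25 at the nominal rate. That rate, like the 2.5% of unchanged lists in the simulation above, does not allow for genes of 1 list that vary together. Cell cycle genes were again higher in 22 of 23 cases (median 0.61, percentile 100), including CCNA2 (0.91), CDC20 (0.89) and CCNB1 (0.89), and MKI67 was at least 1.67-fold higher. NF-kB and inflammatory genes had a median of 0.70 (percentile 100), and of 0.39 without background correction and 0.26 without a detection filter, with CXCL8 at 1.38, CCL20 at 0.81 and IER3 at 0.76, and CXCL1 at least 1.95-fold higher. MYC targets (median 0.47, percentile 100) were led by SRM (0.97) and LYAR (0.81), and the heat shock list (median 0.36, percentile 99.95) by HSPA1B (0.78), HSPH1 (0.75) and DNAJB1 (0.74). Histone genes had a median of -0.82 (percentile 0), with H2BC21 (listed as HIST2H2BE) at least 2.58-fold lower, and all 8 metallothioneins were lower (median -0.51, percentile 0), led by MT1F (-0.91). Ribosomal protein genes had a median of -0.19 (percentile 0.24), with RPL3 at -0.45. Immediate early genes (median -0.32, percentile 0.06) included EGR1 (-1.43) and FOS (-1.01), whereas FOSL1 was at least 1.60-fold higher; this call ended without a detection filter (median -0.16, percentile 2.37) and was kept at -0.20 under median centring. TGF-beta targets (median -0.30, percentile 0.44) included ID3 (-1.36) and ID1 (-1.14), and the call ended under median centring (0.61) and for genes detected in both arrays (0.52). Colon differentiation genes (median -0.28, percentile 0.47), with CDX2 at -0.90 and AGR2 at -0.65 but SPINK4 at 0.99, and cholesterol synthesis genes (median -0.22, percentile 0.32), with SQLE at -0.43, each lost their call in 4 of 10 other settings, where the medians came as near to 0 as -0.04 and -0.16; under median centring cholesterol genes kept it at -0.13. The stress and unfolded protein list did not stand apart here (median -0.19, percentile 1.67), but did so low in 3 of 10 other settings (percentile 0.25 without background correction). ASNS differed by -1.13, PSAT1 by -1.14 and TRIB3 by -0.94, and SESN2 was at least 1.12-fold lower. ISG15 was 2.31-fold and DDX60 at least 1.93-fold lower, and NOTUM at least 2-fold and HILPDA at least 1.98-fold higher.

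**Figure D2:**
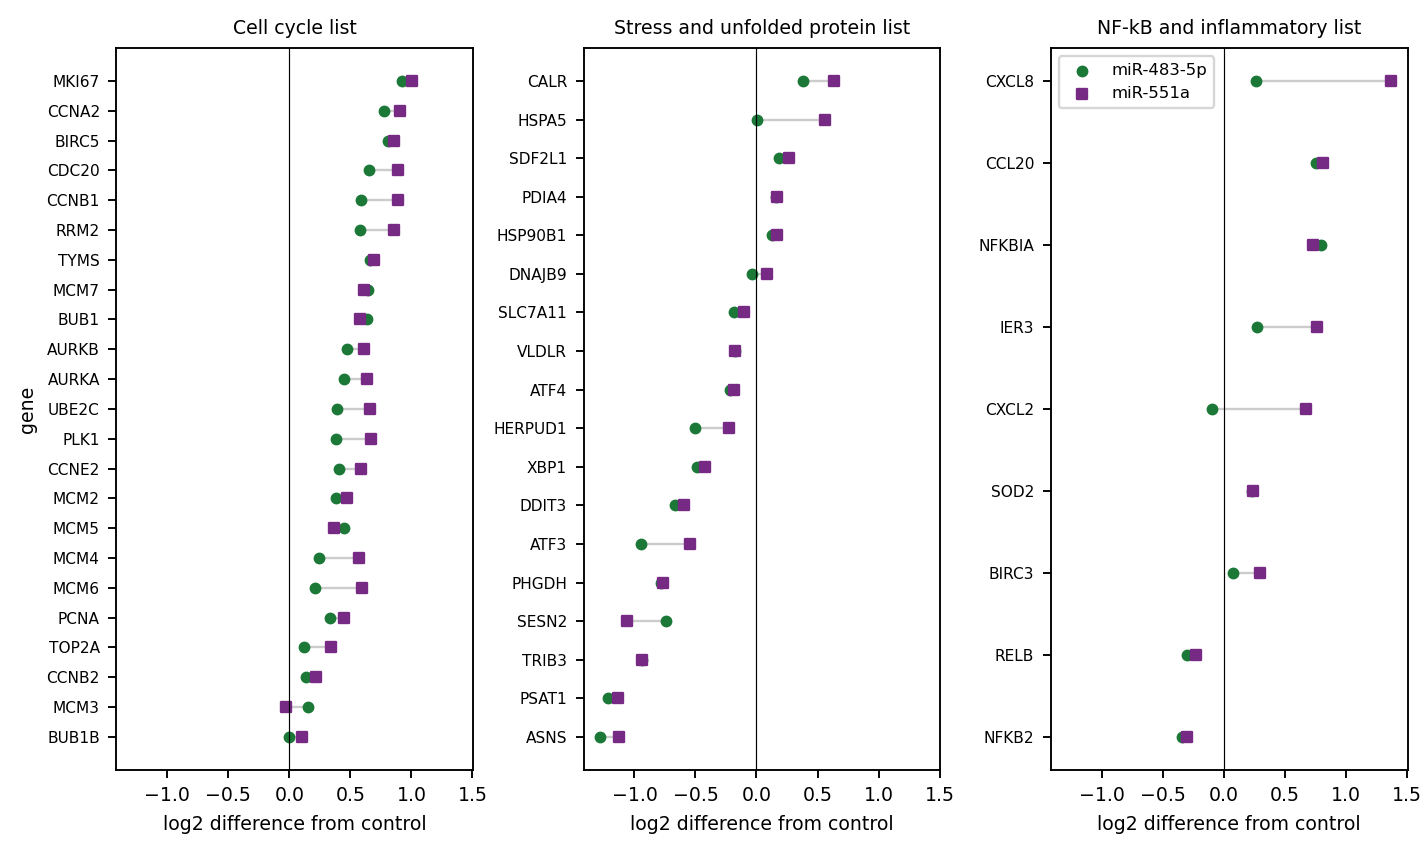
Log2 intensity difference from control (x axis) of each measured gene (y axis) of the cell cycle, stress and unfolded protein, and NF-kB and inflammatory lists; green circles are the miR-483-5p array and purple squares the miR-551a array. CXCL8 lies at 0.27 in the first and 1.38 in the second, while ASNS lies at -1.28 and -1.13.

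The remaining lists did not stand apart in either comparison with control at the main setting. Their medians for miR-483-5p and miR-551a were 0.06 and 0.04 for glycolysis, -0.01 and -0.06 for oxidative phosphorylation, -0.09 and -0.13 for hypoxia, -0.15 and -0.24 for p53 targets, -0.15 and -0.21 for interferon genes, 0.15 and 0.11 for microRNA machinery and 0.14 and 0.04 for housekeeping genes. They were 0.06 and -0.08 for WNT and stem cell genes, 0.03 and 0.06 for apoptosis regulators and 0.02 and 0.03 for epithelial genes. For miR-483-5p, cholesterol (-0.15), colon differentiation (-0.17) and NF-kB genes (0.23) did not stand apart. Ribosomal protein genes (-0.13, percentile 0.89) did not either, but stood apart low in 5 of 9 other settings, with a percentile of 0.03 under median scaling. Hypoxia genes for miR-483-5p stood apart low among brighter probes (median -0.30, percentile 0.13) and had a median of 0.03 with the brightest probe of each gene. Some of these small medians changed sign with the scaling: apoptosis and epithelial genes for miR-483-5p and WNT genes for miR-551a under median scaling, and WNT and oxidative phosphorylation genes for miR-551a under median centring. With other probe filters, colon differentiation genes for miR-483-5p rose as high as 0.05 without a detection filter or among brighter probes. Apoptosis genes changed sign among brighter probes, and the mesenchymal list reached 0.05 without a detection filter, both for miR-483-5p. The mesenchymal list had medians of -0.10 and -0.22 but means of 0.31 and 0.02, because TAGLN was far above its other genes. Markers of other cells were mostly undetected, with 2 of 20 hepatocyte, 4 of 16 leukocyte, 0 of 12 endothelial and 0 of 9 erythroid genes measured, and 5 and 4 of 15 fibroblast genes (median 0.19 but mean -0.01 for miR-483-5p). Among these, LUM was at least 1.58-fold and 2.67-fold higher and FAP at least 2.18-fold and 2.41-fold lower.

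The creatine pathway was examined because creatine kinase B, CKB, is a reported target of both microRNAs. CKB intensity was 510.5 in control, 377.2 in the miR-483-5p and 356.9 in the miR-551a array. After normalization CKB was 1.46-fold lower (-0.54) and 1.63-fold lower (-0.70), both under the 2-fold threshold. Of the 500 probes of like brightness, 2.40% and 2.80% were lower still, and of all probes compared 5.34% and 3.48%. Both differences come from 1 probe and the same control value, so they are not separate observations. The mitochondrial kinases differed less, CKMT1A by 0.05 and -0.03 and CKMT1B by 0.18 and 0.39. The creatine transporter SLC6A8 differed by 0.01 and 0.33, and GAMT by 0.25 and 0.61 at its brightest probe. A further detected GAMT probe differed by 0.27 and 0.12. CKM, CKMT2 and GATM were not detected. Among other reported targets, MAPK3 differed by -0.56 and -0.50 at its 2 probes in the miR-483-5p array and by -0.51 and -0.20 in the miR-551a array. ALCAM (-0.02 and -0.15), SRF (-0.02 and -0.10) and ARHGDIA (0.11 and 0.12) were near control, and 1 PTP4A3 probe was at least 1.41-fold and 1.56-fold lower. Another PTP4A3 probe differed by -0.11 in the miR-483-5p array and was at least 1.25-fold lower in the miR-551a array, and its other probes were not detected. Neither list stood apart: the creatine list had medians of 0.05 (mean -0.01) and 0.33 (mean 0.07; median 0.16 without background correction) at percentiles of 61.8 and 96.7, and the reported targets -0.26 and -0.25 at 1.53 and 3.27. The target median for miR-483-5p was -0.13 without background correction and -0.02 among brighter probes (percentile 46.4). The same 6 targets were used for both arrays, without a split by the microRNA each was reported for, so neither median tests the targets of 1 microRNA.

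The arrays were also compared for genes lower in both, the question in the series title. A group of 56 probes was at least 2-fold lower and 48 at least 2-fold higher in both, of 14207 probes, and 0 went opposite ways at this size. The counts were 12 lower and 13 higher without background correction, 11 and 14 under median scaling, and 13 and 20 among brighter probes. By the smaller of both differences the lower genes were DDIT4, IL33, ASNS, PCK2, ACOX2, GPA33, KIT, PSAT1, TXNIP (2.12-fold and 2.44-fold), ID1, EGR1 and the alanine transaminase GPT2 (2.04-fold and 2.07-fold). The higher genes were KRT17, TAGLN, KRT6B (3.77-fold and 7.76-fold), MUC5AC, S100A10, TRIM29 (2.47-fold and 3.64-fold), FABP5, ALDH1A1, AKR1C2, PLA2G2A, KIFC1 and ANLN. For AKR1C2 this holds at 1 of 2 probes, and the other differed by -0.07 and -0.44. A further probe also fell short of 2-fold in 1 or both arrays for ID1 (-0.18 and -0.94), ASNS (-1.18 and -0.89) and TRIM29 (0.88 and 1.55). Among 3 PCK2 probes the smallest differences were -0.19 and -0.39. A further TAGLN probe was not detected in the control or the miR-483-5p array.

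Both comparisons use 1 control array, which alone makes them alike. Across probes, which are not replicates, the differences correlated at r = 0.731 (Spearman rho 0.693), against 0.50 in simulated unchanged arrays that share a control. All simulated arrays had the same noise, which by itself sets r near 0.50. The simulated values therefore assume a control array no more variable than the others, which these arrays cannot show. The covariance was 0.0994 against a simulated 0.0380, and 56 and 48 shared probes compare with simulated means of 5.25 and 5.12 and with 0.909 and 0.797 for independent lists. With a single control array the excess could not be split, so part or all of it may come from the shared control.

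**Figure D3:**
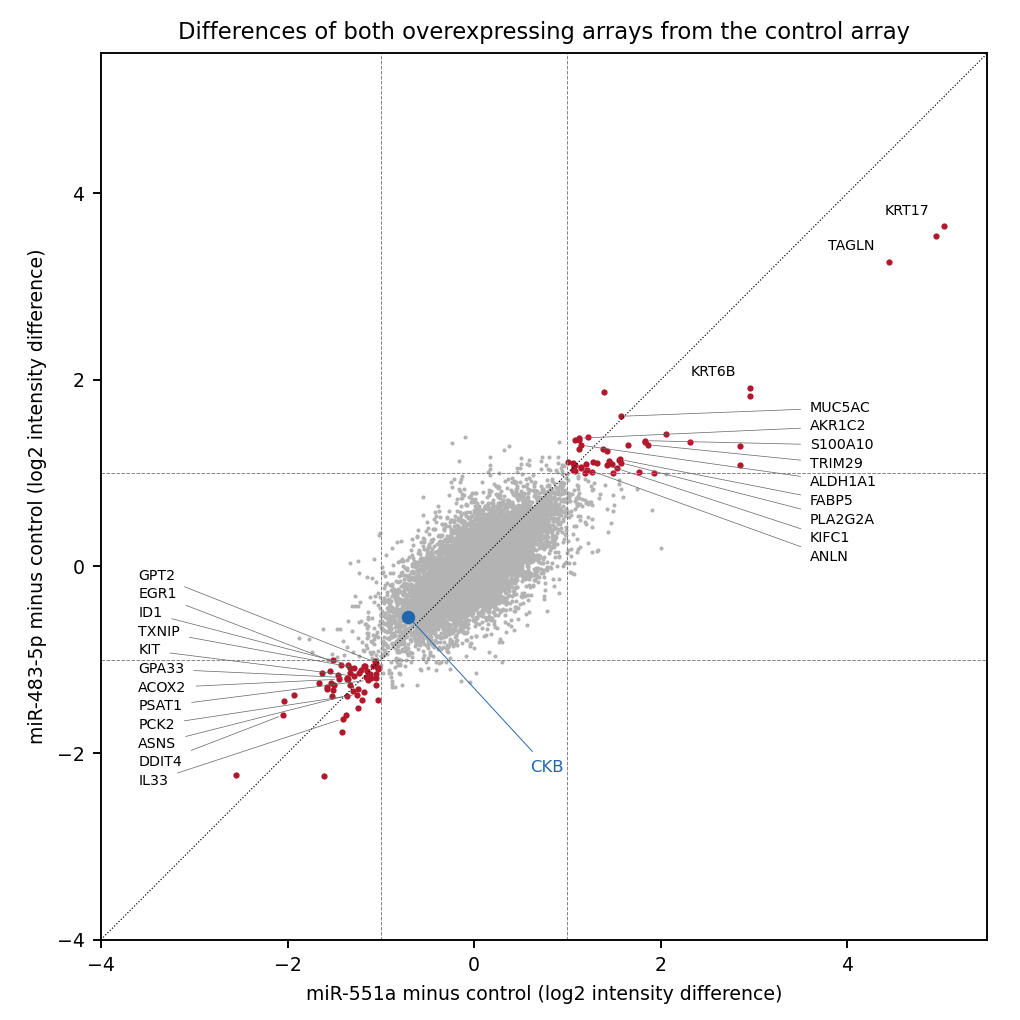
Log2 intensity difference from control of each probe in the miR-551a array (x axis) and the miR-483-5p array (y axis). Red points are at least 2-fold different in the same direction in both (56 lower, 48 higher), dashed lines mark 2-fold, the dotted line marks equal differences, and the blue point is CKB at -0.70 and -0.54.

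The overexpressing arrays were also set directly against each other, without the control. The smooth muscle actin ACTG2 was 2.66-fold lower in the miR-483-5p array than in the miR-551a array. KRT17 was 2.62-fold lower, TAGLN 2.27-fold, CXCL8 2.22-fold, CCN2 (listed as CTGF) 2.07-fold and KRT6B 2.06-fold. ACTG2 was not detected in control and was at least 5.11-fold and 13.6-fold higher in the miR-483-5p and miR-551a arrays, bounds that hold only with the background correction (4.35-fold and 10.1-fold without it). PAQR8 (1.95-fold), the antibacterial enzyme LYZ (1.73-fold), RPS29 (1.69-fold at the probe named above), the autophagy receptor SQSTM1 (1.68-fold), NDRG2 (1.67-fold) and SNHG10 (1.64-fold) were higher in the miR-483-5p array. In all, 25 probes were at least 2-fold higher and 42 lower of 13749, against 0 and 9 under median scaling, and 0 and 7 among brighter probes. Together these are 0.487% of probes, a smaller share than unchanged probes gave in either simulation of miR-483-5p against control, and this difference itself supplied the noise of the simulation based on the arrays. Histone genes (median 0.30, percentile 99.97) and metallothioneins (0.26, percentile 99.97) were higher in the miR-483-5p array, and cell cycle genes (-0.14, percentile 0.13; -0.22 under median scaling) and MYC targets (-0.17, percentile 0.05) lower. Under median scaling the first 2 medians were 0.19 and 0.17. The histone call ended among brighter probes (percentile 77.9) and without a detection filter (94.4). NF-kB genes were lower (-0.22, percentile 0.43), a call that ended in all 8 other settings. The mesenchymal list (0.26, percentile 99.32) and p53 targets (0.13, percentile 97.75) did not stand apart, and still did not in 5 of 8 and 7 of 9 other settings. In the rest they stood apart high. Among brighter probes the p53 median was -0.15. Immediate early genes had a median of 0.11 but a mean of -0.09.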

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

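Median scaling of the non-normalized columns was chosen after the data were seen; the other alternatives were planned. No paired analysis was possible because each group had 1 array. Of 699 list medians recomputed over 76 results, 566 moved by less than the random lists' SD and 133 by more; no list that stood apart changed sign, while some that did not stand apart did. None of 98 differences of named probes, each probe counted once per comparison in which it passed 2-fold, changed sign. As they were picked for passing 2-fold and every setting used the same 3 arrays, a change of sign was unlikely from the outset. Of these 98 differences, 66 stayed 2-fold apart without background correction, 70 with offset 50, 92 under median centring, 94 under cyclic loess and 69 under median scaling, and 37 of 49 in the deposited table. CKB stayed between -0.46 and -0.56 for miR-483-5p and between -0.56 and -0.72 for miR-551a. As there are no replicates, a single value was held to be unmoved within the SD between probes of 1 gene or of the random lists. Counts are given as higher and lower, in the order miR-483-5p against control, miR-551a against control, between the overexpressing arrays, and both. Main counts were 79 and 95, 138 and 134, 25 and 42, and 48 and 56, with r = 0.731 between the differences. Without background correction they were 15 and 19, 47 and 33, 0 and 6, and 13 and 12 (r = 0.772). With offset 50 they were 17 and 21, 51 and 41, 0 and 7, and 15 and 14 (r = 0.767). Median scaling gave 16 and 18, 57 and 28, 0 and 9, and 14 and 11 (r = 0.771), and for miR-551a the deposited table, the same calculation, gave 57 and 28. These settings leave or add background to dim intensities, which shrinks their ratios by construction. Probes detected in every array gave 37 and 49, 81 and 69, 3 and 14, and 30 and 32 (r = 0.764), and probes brighter than the median 18 and 21, 47 and 35, 0 and 7, and 20 and 13 (r = 0.823), in each case from fewer probes tested. Without a detection filter r was 0.641. At 1.5-fold the counts were 554 and 610, 855 and 814, 261 and 332, and 341 and 327. Taking gene means, 16 genes were higher between the overexpressing arrays. Over the alternatives, 2 to 3 lists stood apart high and 5 to 7 low for miR-483-5p (main 3 and 5), 4 high and 4 to 8 low for miR-551a (main 4 and 7), and 1 to 3 high and 2 low between the overexpressing arrays (main 2 and 3). Of these, beyond 1.5 times the main count lay 4 low lists for miR-551a without a detection filter, and 1 high list between the overexpressing arrays without that filter and among brighter probes; the cause was not tested. The deposited normalized table gave no values for miR-483-5p. The seed site alternatives were not run. Signal over background limits these arrays: the median intensity was 84.9 in control against a background mean of 76.2, and 28.3% of its probes were detected.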

Other observations

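Tests on the control culture, stromal transcripts, folding genes and the deposited miR-483 column were chosen after their results were seen; the lists of amino acid, contractile, YAP and NRF2 genes were chosen after the largest differences had been seen but before their own values were.

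Genes for amino acid supply and tRNA charging were lower in both overexpressing arrays beyond those named above. In a list of ATF4-dependent amino acid genes that leaves out ASNS, PSAT1 and PCK2, 20 of 22 measured genes were below control in each array. The seryl-tRNA synthetase SARS differed by -0.91 in the miR-483-5p and -1.12 in the miR-551a array, MARS by -1.07 and -0.74, GARS by -0.83 and -0.78, and the glutamine transporter SLC38A2 by -0.72 and -0.80. SLC1A5 was 2.03-fold lower in the miR-483-5p array but differed by -0.36 in the miR-551a array. KRT16 and MYL9, picked after their values were seen, were not detected in control and were at least 1.24-fold and 1.69-fold higher in the miR-483-5p and 3.67-fold and 3.68-fold higher in the miR-551a array.

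ASNS, PSAT1 and PCK2 were lower in both arrays. A fall of the whole unfolded protein response is argued against only by a test chosen after its result was seen. The folding genes HSPA5, HSP90B1, DNAJB9, SDF2L1, PDIA4, CALR and DNAJC3 had medians of 0.14 (6 measured) and 0.27 (7 measured), so as a set these genes were not lower. A wider fall of ATF4 amino acid genes is a candidate explanation: without the 3 genes the list medians were -0.59 and -0.43, with a percentile of 0 in the weaker comparison, below all random lists. The shared control culture stays open, since a control with high amino acid stress would give the same values.

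Both difference profiles run together. Scatter of single probes on the shared control array is argued against as the whole cause: over 2553 genes, the covariance between different probes of a gene was 0.548 of that at the same probe (interval 0.503 to 0.591), just above the preset bound of 0.5, so a sizeable part may still be scatter at single probes. RNA of the single control culture cannot be told apart from an effect common to both microRNAs: the covariance exceeded the simulated one by 0.0615, and 1 control culture gives no means to split it. That common effect, named by the design, was not tested.

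TAGLN, ACTG2 and MYL9 were higher in both arrays. Stromal or smooth muscle cells are argued against only by a test chosen after its result was seen. In it, 1 of 12 abundant stromal transcripts (LUM) was detected and at least 2-fold higher in the miR-551a array, and ACTA2, COL3A1 and LGALS1 were below control. A wider rise of contractile SRF target genes was not seen in the miR-483-5p array. The medians were -0.14 and 0.09, with a weaker percentile of 5.64 over 11 genes that went both ways. It stays open only because the preset bound against it was the 2.5 percentile. A wider rise of YAP targets was not seen in the miR-483-5p array either, and stays open by the same bound. Its medians were -0.17 and 0.16, with a weaker percentile of 9.84.

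AKR1B10 and 1 of 2 AKR1C2 probes were higher in both arrays, and a wider rise of NRF2 targets was tested as a hypothesis. The other AKR1C2 probe differed by -0.07 in the miR-483-5p and -0.44 in the miR-551a array. The 11 targets had medians of 0.12 and -0.00, with a weaker percentile of 54.6. No wider rise was seen in the miR-551a array, where 5 of the 11 were above control. The hypothesis stays open only because the preset bound counted a median against it below the 2.5 percentile, which an unchanged list would not reach.

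The ratio of the deposited normalized miR-483 column to the normalized miR-551a column was 0.965 at every probe, equal to the control median over the miR-483-5p median. The non-normalized columns of these arrays were not near-identical, with ratios from 0.375 to 1.80.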
